A study of Homo sapiens with 11 samples.

How the data were processed

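The series held 11 arrays of IMR-32 cells, a human neuroblastoma line, after 24 h with 10 µM tert-butylhydroquinone (tBHQ) or with the ethanol vehicle at 0.01%. Total RNA was measured on 2 array types. The first set held 8 GeneChips, short-oligonucleotide arrays that carry 1 sample each, with 4 vehicle and 4 tBHQ arrays. The second set held 3 long-oligonucleotide arrays (oligoarrays), each carrying 2 samples in 2 channels, tBHQ in the first and vehicle in the second, per the labels. Groups were taken from the labels. The GeneChip labels also give the day of harvest, and each of the 4 harvests supplied 1 vehicle and 1 tBHQ array. Nothing in the labels says whether the 3 oligoarrays came from separate cultures or from the cultures used on the GeneChips, so their p-values measure only the spread between arrays, which may be technical.

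For the GeneChips, the authors deposited 1 linear intensity (signal) per probe set. The image analysis, background correction and summary of probes are not given in the sources used here. The deposited signals had already been brought to a common level: the trimmed means of the 8 arrays, leaving out 2% at each end, differed by at most 0.0224%. They were therefore used without further scaling. For the oligoarrays, the authors deposited 1 log ratio per row, and the normalization, the dyes, the base of the logarithm and the direction of the ratio are not given in the sources used here. The base was taken as log10. Over 10 antioxidant response element genes measured on both platforms, the median deposited value per GeneChip log2 unit was 0.295, where log10 predicts 0.301 and a natural log 0.693. The single genes ranged from -0.232 to 0.409, so the base remains an inference. The direction was taken as tBHQ over vehicle, the order of the channels in the labels, and NQO1, GCLM and AKR1C3 were then higher with tBHQ on both platforms. This direction is likely and not stated. The median deposited log10 ratios were 0, -0.000858 and 0.000779 on arrays 1, 2 and 3.

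GeneChip signals below the 10th percentile of all values, a signal of 106.2, were raised to it, and log2 was taken. The 67 control probe sets were left out, and the 60% of probe sets with the highest mean log2 signal were tested, 7535 in all. The tBHQ and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). The main fit was unpaired, and a second fit held the harvest as a block. The harvest numbers pair the samples, since the labels give a shared harvest day. The correlations of deviations from the group means within harvests 1 to 4 were 0.37, 0.26, 0.68 and 0.42, and the highest with an array of another harvest were 0.38, 0.38, -0.19 and 0.12. For harvests 1 and 2 the values alone would not show the pairing, which rests on the labels. Oligoarray ratios were turned into log2. Rows at the deposited limit of -2, which carried no gene, were left out, and 18590 rows with a value on all 3 arrays were tested against 0 with lmFit and eBayes. Because the vehicle sat in the second channel of each array, this test has no separate measure of the spread between vehicle samples, and a fixed dye effect would add to every ratio. All adjusted p-values used the Benjamini-Hochberg method with a threshold of 0.05, and all tests were two-sided. The number of arrays limits the precision.

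Genes were named from the platform annotations of 2016 (GeneChip) and 2008 (oligoarray), with symbols updated through gene identifiers in the RefSeq table of assembly GRCh38.p14. On the GeneChips 10961 probe sets had 1 gene, 545 several and 1119 none, and 10949 of the first were matched by identifier. On the oligoarrays 15695 rows had 1 gene, 4 several and 3362 none, with 15650 matched. Probe positions in the genome were not used here. For comparisons of genes, the probe set with the highest mean signal stood for a gene on the GeneChips and the mean of its rows on the oligoarrays, which gave 5548 and 14227 genes and 5030 shared ones. The platforms' changes were correlated over shared genes, with 10000 random pairings and 2000 bootstrap draws of genes, and genes are not independent replicates. The difference between platforms was tested with limma on 7 ratios, 4 from harvests and 3 from oligoarrays.

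Before the data were examined, 20 gene lists were fixed. Each was tested against all other genes with camera in limma at a preset correlation of 0.01 and again with an estimated correlation. The tool fry asked whether a list's genes moved on balance in 1 direction, or in either. Named genes followed a rule fixed at the same time. On each platform it takes the 15 largest increases and the 10 largest decreases among called features with 1 gene and the same direction in all harvest pairs or on all arrays. Where fewer than 5 passed, the 5 with the lowest p were given as values. It adds up to 15 genes called alike on both platforms, up to 5 called in opposite directions, the 10 with the largest tested platform difference, taken in order of p, and 2 to 4 members of each list with the largest change that passed, or the 2 largest as values. NQO1, HMOX1, GCLM, GCLC, TXNRD1, NFE2L2, KEAP1, ACTB and GAPDH were always given. List members outside this rule (AKR1C1, PIR, TKT, UGDH, PGD and GSTM4 on the oligoarrays, and the genes named at an unadjusted p across platforms) were chosen after their values were seen. Alternatives fixed in advance were the harvest block, quantile or median scaling, other floors and signal filters, a fit without variance trend, a robust prior, centring and scaling of the ratios, another value per gene, and leaving out each array.

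The fits were tested on simulated data with known changes in 50 features per size. Over 7535 probe sets, the unpaired GeneChip fit recovered 0% of 2-fold, 34% of 4-fold, 82% of 8-fold and 84% of 16-fold changes with 0 false calls, and the block fit 32%, 60%, 90% and 98% with 4 false calls. Over 18590 rows, the oligoarray fit recovered 0% of 1.2-fold, 44% of 1.5-fold, 58% of 2-fold and 86% of 4-fold changes with 5 false calls. On the real oligoarrays 47.5% of rows were called, which makes the adjusted threshold less strict there than in the simulation. Over 5030 genes, the platform test recovered 38% of 2-fold and 80% of 4-fold differences with 14 false calls. A later simulation with the same spreads took the oligoarray mean ratios as gaps between the platforms. It called a median of 130.5 genes, where the data gave 1. The shares recovered therefore describe the simulated settings and may not hold for the data. In the simulated GeneChip lists over 5548 genes, camera called the list of 23 members shifted by 0.5 log2 units and 0 of 19 others. Figures were drawn with matplotlib 3.10.9.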

Results

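IMR-32 cells, a human neuroblastoma line, were compared after 24 h with 10 µM tBHQ, a phenolic antioxidant that activates the transcription factor NRF2, and after ethanol vehicle. The series sets long-oligonucleotide arrays beside short-oligonucleotide GeneChips. There were 4 vehicle and 4 tBHQ GeneChips from 4 harvests and 3 oligoarrays with both samples on each array. The median GeneChip signal was 786 to 982 on 6 arrays and 1311 and 1333 on the vehicle and tBHQ arrays of harvest 3. The 6 arrays correlated with each other at r = 0.82 to 0.97 over log2 signals of probe sets, and with the arrays of harvest 3 at r = 0.67 to 0.72. The ratios of the 3 oligoarrays correlated with each other at r = 0.79 to 0.86 over the shared genes. On the GeneChips, the changes of 2 harvests correlated at r = -0.027 to 0.062 over these genes. These correlations are not like measures. The oligoarrays may be technical repeats, and a fixed dye effect would raise their r, while the GeneChip changes come from separate harvests.

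The first comparison asked which transcripts differed between tBHQ and vehicle on the GeneChips. NQO1 (probe set 38066_at) is a quinone-reducing enzyme and a standard NRF2 target. Its signal was 1989 ± 428 (SD, n = 4) in vehicle and 9862 ± 3489 (SD, n = 4) with tBHQ. Folds are ratios of geometric means, here 4.80-fold, a log2 change of 2.26. AKR1C3 (37399_at), an aldo-keto reductase, had 606 ± 383 (SD, n = 4) and 9659 ± 9795 (SD, n = 4), 13.1-fold. Both were higher in 4 of 4 harvests. Neither passed in the unpaired limma fit (adjusted p = 0.158 and 0.411), and both rose in the fit with harvest as a block (adjusted p = 0.00894 for each). With the block, 1 more probe set rose, 32805_at, which is annotated to several genes (9.09-fold, adjusted p = 0.0217). Its vehicle signal at harvest 3 was 105.4, just below the floor of 106.2. AKR1C3 belongs to a family of near-identical genes, so its signal may hold transcripts of its relatives.

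Over all 7535 probe sets, limma called 0 higher and 0 lower with tBHQ in the unpaired fit. At an unadjusted p under 0.05 there were 74, 48 higher and 26 lower, where chance alone gives 376.75 for independent arrays. Differences between harvests stay in the error of this fit, so its low counts say little about tBHQ. A split into harvests 1 and 2 against harvests 3 and 4 gave 1491 at that unadjusted threshold. The fit with harvest as a block called 3 higher and 0 lower, with 388 at an unadjusted p under 0.05, close to the 376.75 that chance gives. The 3 calls with the block depended on which harvest was left out. They fell to 0 without harvest 1 or harvest 2 (291 and 337 at an unadjusted p under 0.05), to 1, NQO1, without harvest 4, and without harvest 3 the same 3 were called with 1 lower, EEF1A1. The changes themselves moved less: without any 1 harvest the log2 change was 2.10 to 2.49 for NQO1, 3.45 to 4.26 for AKR1C3 and 2.73 to 3.63 for 32805_at.

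The other genes named by the rule did not pass over all probe sets and are given as values. GCLM (33163_r_at), the regulatory subunit of the enzyme that limits glutathione synthesis, had a log2 change of 1.65 ± 0.21 (SD of 4 harvests; adjusted p = 0.9998 unpaired and 0.218 with the block). TXNRD1 (39425_at), thioredoxin reductase, had 1.04 ± 0.22, and WASF2 (35126_at), a regulator of actin assembly, 2.13 ± 0.60. GCLC, the catalytic subunit of glutathione synthesis, had 0.67 ± 0.55 and KEAP1, which holds NRF2 in check, 0.74 ± 0.48. NFE2L2, the gene of NRF2, had -0.21 ± 0.39. HMOX1, heme oxygenase, lay below the signal filter, at 190.9 ± 107.7 (SD, n = 4) in vehicle and 577.5 ± 299.1 (SD, n = 4) with tBHQ. The lower values with the smallest p belonged to RIPOR2 (32977_at, -2.09 ± 0.96), SLITRK5 (33576_at, -1.48 ± 1.01), the calcium channel subunit CACNG3 (36764_at, -1.44 ± 0.74), SMTN (31831_at, -1.22 ± 0.09) and the translation factor EEF1A1 (1288_s_at, -0.97 ± 0.67), each with an unpaired adjusted p of 0.9998. Of the reference genes, ACTB had 0.42 ± 0.45 and GAPDH -0.91 ± 5.44. The vehicle signal of GAPDH was 57.7 at harvest 2 and 43410 to 110130 at the other 3. Its tBHQ signals were also spread widely, from 453.6 at harvest 1 to 140080 at harvest 3.

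**Figure D1:**
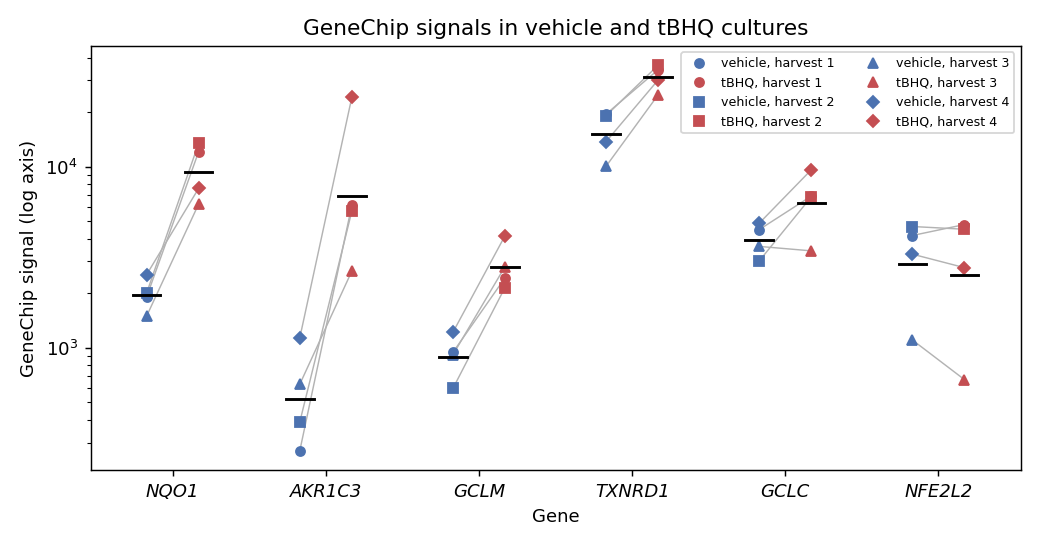
GeneChip signal (log axis) of 6 genes in the 4 vehicle (blue) and 4 tBHQ (red) cultures, with grey lines joining the arrays of a harvest and black bars at the geometric mean. NQO1 signals were 1497 to 2538 in vehicle and 6234 to 13486 with tBHQ, and AKR1C3, GCLM and TXNRD1 were also higher in 4 of 4 harvests.

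The gene lists fixed beforehand were tested next. Of the 23 tested members of the list of NRF2 and antioxidant response element targets, 23 had a higher mean with tBHQ and 0 a lower one, with a median log2 change of 0.52. None passed over all probe sets and 2, NQO1 and AKR1C3, did so with the harvest block. Adjusted over the list alone, 6 rose: AKR1C3, NQO1, GCLM, ME1, TXNRD1 and the pentose phosphate enzyme TKT (0.99 ± 0.24). Camera placed the list above all other genes (adjusted p = 1.98e-15), a call lost with an estimated correlation (adjusted p = 0.0661). The list's mean shift of 0.79 was the largest of the 35 splits of the 8 arrays (exact permutation p = 0.0286), which ignore the harvest pairs. In fry the shift had an adjusted p of 0.108 unpaired and 0.0113 with the block. Without both arrays of harvest 3, left out after seeing the data, the median was 0.42.

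Of the related lists, glutathione synthesis and use had 13 of 22 members higher (median 0.04) and the thioredoxin and peroxiredoxin system 8 of 12 (median 0.14), with 1 member each, GCLM and TXNRD1, past the threshold adjusted over the list alone. NADPH production had 8 of 11 higher (median 0.12), with ME1 (1.26 ± 0.81) and TKT past that threshold. GCLM, TXNRD1, ME1 and TKT also belong to the antioxidant response element list. Camera called none of these lists (adjusted p = 0.276, 0.314 and 0.159), while fry for changes in either direction passed with the harvest block (adjusted p = 0.00106, 0.00683 and 0.00683) and missed without it (0.905 for each). Iron and heme metabolism had 8 of 11 members higher with no call (camera adjusted p = 0.181). The list of cell cycle and DNA replication genes lay below the other genes (camera adjusted p = 0.0116), a call lost with an estimated correlation (adjusted p = 0.833). Of its 34 members 28 had a lower mean and none passed, also adjusted over the list alone. Its median was -0.20, and BIRC5, which blocks cell death in mitosis, had -0.68 ± 0.59 and the proliferation marker MKI67 -0.57 ± 0.56. In the exact permutation test over unpaired splits its mean shift was reached by 17 of the 35 splits (p = 0.486). Within harvests 1 to 4 its median was -0.14, -0.39, -0.16 and -0.22, and with the harvest block the camera adjusted p was 0.00579, or 0.551 with an estimated correlation. Among the 8 splits that part all 4 harvest pairs, a comparison added after seeing the data, the real one was the largest, which allows an exact p of 0.125 at the smallest. Camera called none of the proteasome subunits (21 of 32 higher, adjusted p = 0.159), heat shock proteins and chaperones (8 of 17 higher, 0.159), endoplasmic reticulum stress (11 of 20 higher, 0.825), immediate early genes (3 of 14 higher, 0.204) or p53 targets (10 of 16 higher, 0.499).

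The second comparison asked the same of the oligoarrays, whose direction is likely tBHQ over vehicle. NQO1 (row 14042) had a log2 ratio of 2.98 ± 0.21 (SD of 3 arrays), 7.90-fold, followed by AKR1C3 (row 515) at 2.84 ± 0.11 and GCLM (row 12513) at 2.24 ± 0.03, 4.73-fold. FTL, the light chain of the iron store ferritin, had 2.04 ± 0.03 and HMOX1 1.22 ± 0.08. The limma adjusted p of these 5 was 0.00619 each, and all were above 1 on 3 of 3 arrays. TXNRD1 (0.57 ± 0.09), GCLC (0.55 ± 0.08) and NFE2L2 (0.16 ± 0.01) also had ratios above 1 (adjusted p = 0.00849, 0.00800 and 0.0246), and KEAP1 did not pass (0.09 ± 0.03, adjusted p = 0.0991). The reference genes had ratios below 1, at -1.09 ± 0.03 for GAPDH and -1.13 ± 0.05 and -0.94 ± 0.03 for both rows of ACTB, also after centring each array on its median.

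Of the 18590 rows, 4358 had a ratio above 1 and 4469 below 1 at the threshold, 47.5% in all. Of these, 309 were at least 2-fold above and 376 at least 2-fold below. The count rests on 3 arrays. Without array 1 or array 2 it was 0 in each direction (8173 and 7624 rows at an unadjusted p under 0.05), and without array 3 it was 2654 above and 3159 below. The other 11 of the 15 largest ratios above 1 were single rows of C3orf36 (2.30), DHRS7C (2.24), APBB1IP (2.17), the gastric proton pump subunit ATP4A (2.14), the matrix protease MMP7 (2.13), CEACAM6 (2.13), PPEF2 (2.08), SCML4 (2.08), EGR3 (2.07), PLA2G4A (2.02) and GPR65 (2.01). PLA2G4A had 9 further rows at 0.52 to 1.13, and the mean of its rows was 0.96. The 10 largest below 1 were POU4F3 (-3.01), the olfactory receptor OR10Z1 (-2.88), the liver fatty acid carrier FABP1 (-2.71), CAVIN1 (-2.44), CACNA2D3 (-2.33), ADAMTSL4 (-2.27), CD1D (-2.21), ODAD2 (-2.19), F2RL2 (-2.19) and LRP2 (-2.16). ADAMTSL4 and ODAD2 each had a second row that was not below 1 (0.20 ± 0.01, adjusted p = 0.0165, and 0.09 ± 0.09, adjusted p = 0.212), and the means of their rows were -1.04 and -1.05. Of the 15 largest above, 11 were on the GeneChips and 5 passed their signal filter, and of the 10 below, 5 and 1. The mean GeneChip signals of GPR65 (83.95), F2RL2 (74.65) and FABP1 (105.6) lay below the floor of 106.2.

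On the oligoarrays, 26 of 36 members of the NRF2 and antioxidant response element list were above 1 and 3 below, and 27 and 3 adjusted over the list alone, with a median log2 ratio of 0.52. AKR1C1, a close relative of AKR1C3, had 1.71 ± 0.04, PIR 1.49 ± 0.04 and TKT 1.24 ± 0.01, while UGDH had -0.36 and PGD -0.32. Camera placed the list above the other genes (adjusted p = 5.65e-06), a call lost with an estimated correlation (adjusted p = 0.539). The estimate was -0.023, below the preset 0.01, so the loss does not come from correlated members. With estimated correlations no list on the 3 oligoarrays had a camera adjusted p under this 0.539, so the loss says little about this list. Iron and heme metabolism had 8 of 14 members above 1 and 0 below, among them FTL, HMOX1 and FECH (0.98 ± 0.11), the enzyme that inserts iron into heme (camera adjusted p = 0.0484). FTL and HMOX1 also belong to the antioxidant response element list, so the lists are not separate evidence. The proteasome subunits had 19 of 34 above, such as PSMA6 (0.57 ± 0.06), and 5 below, such as the activator subunit PSME3 (-0.86 ± 0.10; camera adjusted p = 0.0438). Both calls were lost with an estimated correlation (adjusted p = 0.699 for each). Of 33 cell cycle and DNA replication genes, 20 were below 1 and 3 above, with a median of -0.29. They included the transcription factor FOXM1 (-0.91 ± 0.10), the replication helicase subunit MCM5 (-0.90 ± 0.04) and cyclin D (CCND1, -0.85 ± 0.17). The list's camera adjusted p was 0.000879, and 0.699 with an estimated correlation.

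**Figure D2:**
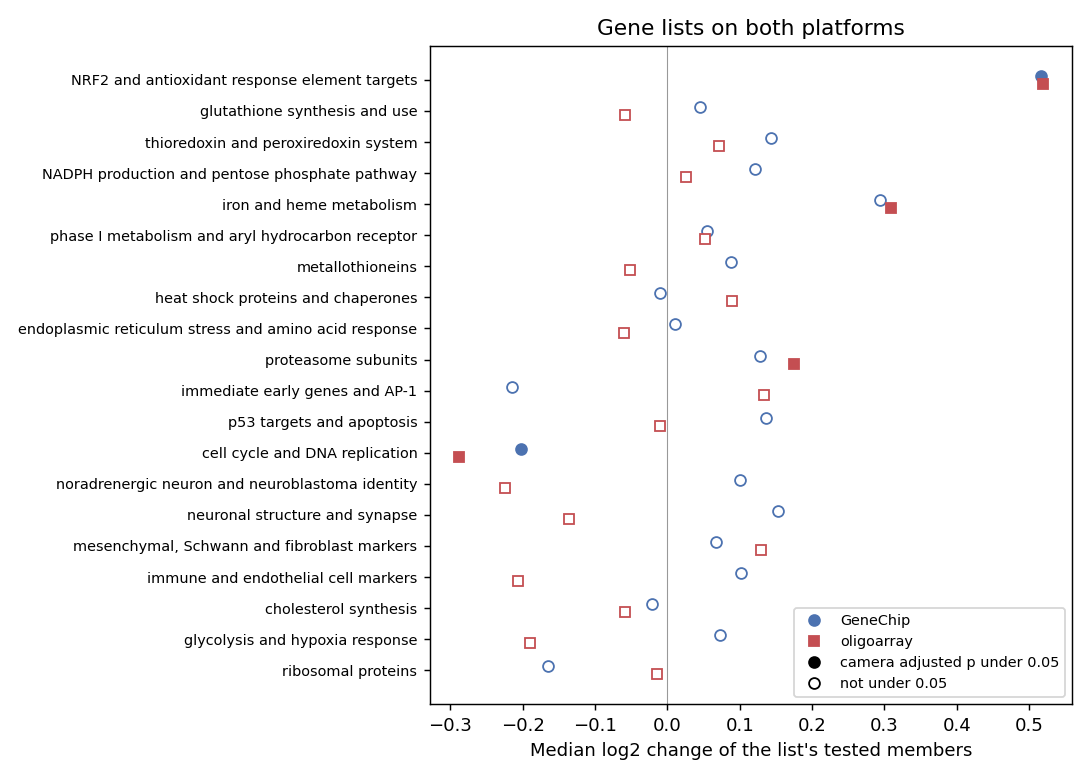
Median log2 change of the tested members of the 20 fixed gene lists on the GeneChips (blue circles) and oligoarrays (red squares), filled where the camera adjusted p at the preset correlation was under 0.05. The antioxidant response element list had medians of 0.52 on both platforms, and the cell cycle list -0.20 and -0.29. The base of the oligoarray logarithm was inferred from 10 genes of the first list, so its equal size on both platforms is partly built in.

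The other stress lists held members on either side. Glutathione synthesis and use had 9 of 27 above 1 (GCLM; GSR, 1.12 ± 0.04) and 11 below (GSTM4, -0.63 ± 0.15). The thioredoxin list had 6 of 15 above (TXN, 0.66 ± 0.19) and 6 below (TXN2, -0.94 ± 0.10), and NADPH production 5 of 12 above (TKT; ME1, 0.79 ± 0.18) and 4 below (PGLS, -0.59 ± 0.01). Heat shock proteins had 5 of 19 above (HSPA8, 0.51 ± 0.03) and 7 below (HSPB1, -0.65 ± 0.06). Endoplasmic reticulum stress had 6 of 28 above and 11 below (ATF4, -0.76 ± 0.06; CALR, -0.68 ± 0.11), p53 targets 7 of 22 above and 8 below (BAK1, -0.83 ± 0.06), and immediate early genes 5 of 17 above (EGR3, 2.07 ± 0.36) and 2 below (JUND, -0.94 ± 0.10). Camera called none of these 7 lists, with the lowest adjusted p of 0.258 for the immediate early genes. Fry, which does not compare a list with the other genes, passed in 1 direction for 6 of the 7, among them glutathione synthesis and endoplasmic reticulum stress (adjusted p = 0.00167 for each), NADPH production (0.0106) and heat shock proteins (0.0159), and missed for the thioredoxin list (0.0660). It passed for 16 of all 20 lists in 1 direction and for 20 in either, on arrays where 47.5% of rows were called. Medians and means differed in sign for glutathione synthesis (-0.06 and 0.11), the thioredoxin list (0.07 and -0.00087) and heat shock proteins (0.09 and -0.05), and camera ranked these up, up and down.

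The third comparison, which the series title names, set the platforms side by side. Over 5030 shared genes the changes correlated at r = 0.04 and rho = 0.01 across genes, where 95% of random pairings gave r between -0.027 and 0.028 (permutation p = 0.0088 for r). The bootstrap interval of r, -0.002 to 0.082, held 0, and r was -0.016 without the vehicle array of harvest 2 and -0.005 without the tBHQ array of harvest 3. Since the GeneChip changes of separate harvests correlated at only r = -0.027 to 0.062, a low r here does not show that the platforms disagree. Within the antioxidant response element list r was 0.82 and rho 0.73 over 23 genes (permutation p = 1e-04 for r, the smallest that 10000 pairings can give), and r was 0.71 and rho 0.65 without the 2 members farthest from the median GeneChip change. A set of 23 random genes reached that r in a share of 0.001. Outside the list r was -0.002, a split added after seeing the data. The sign was the same for 17 of the 23 list members and for 50.9% of all shared genes. These values rest on the direction of the oligoarray ratio: turned, a calculation added after seeing the data, they would be 6 of 23 and 49.1%, with r = -0.82 within the list and -0.04 over all shared genes. The direction leaned on the list members NQO1, GCLM and AKR1C3, so the sign of r within the list is not independent of that choice.

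**Figure D3:**
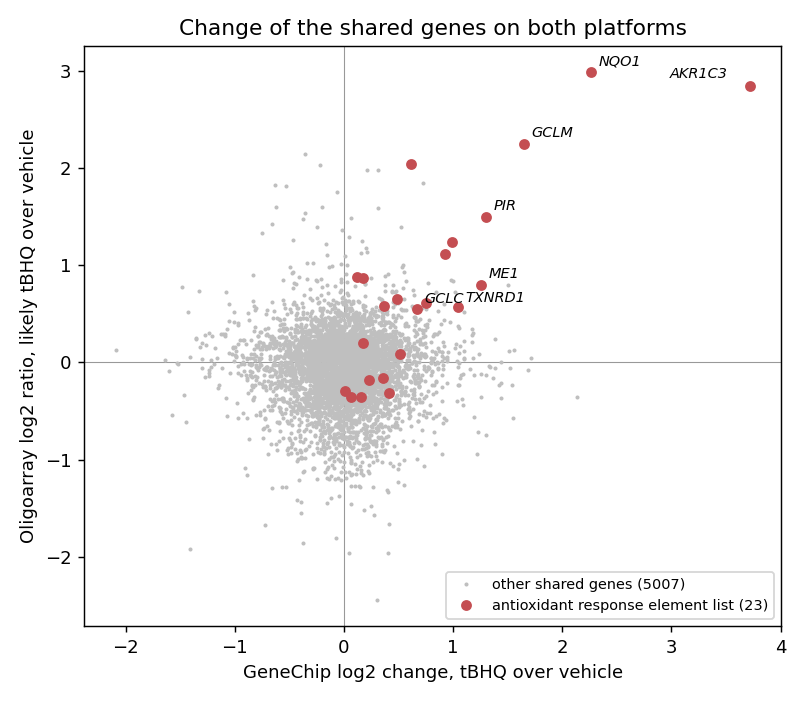
Log2 change on the GeneChips (horizontal axis) and log2 ratio on the oligoarrays (vertical axis) for 5030 shared genes, with the 23 members of the antioxidant response element list in red. AKR1C3, NQO1 and GCLM lie far from 0 on both axes, and the other genes show no common slope (r = -0.002 outside the list).

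With the unpaired GeneChip fit, 0 genes were called in the same direction on both platforms. With the harvest block 2 were, NQO1 and AKR1C3 (0.472 expected from independent calls, Fisher's exact p = 0.0557). The likely direction of the ratio leaned on NQO1, AKR1C3 and GCLM being higher on both platforms, so their shared direction is not independent support. In the block fit at an unadjusted GeneChip p under 0.05, a threshold added after seeing the data, 47 of 140 higher genes had an oligoarray ratio above 1 (33.0 expected, Fisher's exact p = 0.00631), among them GCLM, TXNRD1, PIR, TKT and ME1, and 35 had a ratio below 1 (45.1 expected, Fisher's exact p = 0.0668). Of 117 lower genes, 33 had a ratio below 1 (37.7 expected, Fisher's exact p = 0.369), among them CCNA2 and CCNB2, and 22 above 1 (27.6 expected, Fisher's exact p = 0.270). Over all probe sets the block fit had 388 at that threshold where chance gives 376.75, so many of the 140 and 117 genes may be there by chance. These Fisher's exact p-values were not adjusted for the number of comparisons. In all, 80 genes had the same direction and 57 the opposite one, and 14 and 11 in the unpaired fit at that threshold. Among the 57 were PGD (0.41 on the GeneChips and -0.32 on the oligoarrays), ACTB (0.42 and -1.03) and ALDOA (0.91 and -0.57). With the oligoarray ratios turned, the 80 and 57 would change places, and NQO1 and AKR1C3 would be called in opposite directions. The spread between replicates differed in size: the median SD was 0.53 over the 4 harvest changes and 0.06 over the 3 oligoarrays, at median absolute changes of 0.22 on both, given the inferred log base. The oligoarrays may be technical repeats, so these SDs do not rank the platforms.

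A difference between platforms passed for 1 gene, SERPINA4, a serine protease inhibitor, with -0.63 ± 0.20 on the GeneChips and 1.82 ± 0.17 on the oligoarrays (limma adjusted p = 0.0167). At an unadjusted p under 0.05 there were 721. The count was 0 without any 1 of the oligoarrays or of harvests 1 to 3, and 2 without harvest 4. The call depends on the direction of the oligoarray ratio. With every ratio turned, a fit added after seeing the data, SERPINA4 would have -1.82 on the oligoarrays and a difference of -1.19 (adjusted p = 0.0922), and 8 other genes would be called, among them NQO1, AKR1C3, GCLM and TXNRD1. The 9 genes next in order of p missed the threshold, among them SMAD4, a mediator of growth factor signals (0.25 and -1.47), and PKM, pyruvate kinase (0.40 and -1.96; adjusted p = 0.0590 for both). MAP3K13, POLD4, CD151, ATP4A, UCP2 and NUCB1 had an adjusted p of 0.0878 each and TBX1 0.0959. The order is not one of size, as the difference of ATP4A (-0.36 and 2.14) was larger than the 2.45 of SERPINA4.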

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

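Tests of beta-actin and spike controls on the harvest 3 arrays, of turned oligoarray ratios and of simulated platform ratios were chosen after the results were seen. The others in this part were set beforehand.

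The platforms differed for SERPINA4, whose oligoarray ratio exceeded its GeneChip change by 2.45 log2 units. No other of the 35 splits of the 7 ratios into 4 and 3 called a gene (1 of 35 as large, highest other 0). This is not taken to exclude chance, since the other splits mix ratios of unequal spread and ratios simulated without any difference gave a call in 12 of 100 runs. With the oligoarray ratios turned, the difference was -1.19 and did not pass. The count fell to 0 with no signal filter and without any 1 of the oligoarrays or of harvests 1 to 3.

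For the arrays, 80 groups of 4 were searched for a value far from the other 3, and 10 were found where chance gives about 4. On the tBHQ array of harvest 3 the mean log2 signals of the lists for NADPH production (12.16), neuronal structure (12.46), mesenchymal markers (10.92) and immune and endothelial markers (11.37) stood apart. On the vehicle array of harvest 3 this held for the median signal (1311), metallothioneins (12.43), proteasome subunits (12.32) and neuronal structure (12.34). The log2 signal of GAPDH stood apart on the vehicle array of harvest 2 (6.731, the log2 of the floor of 106.2, to which its signal of 57.7 was raised). The mean of the cholesterol synthesis list stood apart on the tBHQ array of harvest 4 (12.91).

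Both GeneChips of harvest 3 thus stand apart from the other 6. Their ratio of 3' to 5' signal for beta-actin was 3.32 and 3.56, against 1.19 to 2.56 on the others, as degraded RNA or incomplete cDNA would give, although the same ratio for GAPDH (1.32 and 1.70, others 0.812 to 1.61) did not separate both. Their bacterial spike controls averaged 59702 and 70543, against 13300 to 44811, as less labelled sample relative to the spikes would give. Both may hold at once, and no biological explanation was tested. Because vehicle and tBHQ share the harvest, the block removes the common part, and without harvest 3 the block fit called 3 probe sets higher and 1 lower.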

How the results depend on the processing

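The unpaired fits without harvest 3, the comparisons at an unadjusted p, the turned ratios, the correlations within and outside the antioxidant response element list and the values of its oligoarray members measured on the GeneChips were added after the data were seen. The GeneChip counts of 0 held in the unpaired limma fits under quantile and median scaling, both other floors, both other filters, no variance trend and without any 1 array (39 to 252 probe sets at an unadjusted p under 0.05). The replicate block gave 3 higher; with the replicate block and without harvest 3 there were 3 higher and 1 lower, and without harvest 4 there was 1 higher. The block raised the genes called alike on both platforms from 0 to 2, and apart from the values given with the gene lists it changed no other call. At an unadjusted p under 0.05 they numbered 14 in the unpaired fit, with 11 opposite, and 80 with the block, with 57 opposite. The oligoarray counts stayed within 1.5 times under centring, scaling and a robust prior, and ranged from 0 to 2654 above and 0 to 3159 below without any 1 array, where fewer arrays were fitted. Accepting values on 2 arrays added no row. The platforms' correlation was 0.0902 with the stricter signal filter, -0.016 to 0.0733 without any 1 array, -0.0372 with the oligoarray ratios turned and 0.819 within the antioxidant response element list. The genes differing between platforms numbered 0 with no filter, 3 with the stricter filter, 8 with the oligoarray ratios turned and 0 to 2 without any 1 ratio. They numbered 3592 when GeneChip ratios were multiplied by the slope, which by construction shrinks them and their spread towards 0. Where no construction is named, the cause was not tested. The antioxidant response element list lost its camera call with the estimated correlation, which leaves its medians at 0.516 and 0.52. It kept the call with the block and without the filter (GeneChips), and without any 1 array, at medians of 0.478 to 0.741 on the GeneChips and 0.465 to 0.549 on the oligoarrays. It also kept it without harvest 3 (0.42) and for the oligoarray members measured on the GeneChips (0.607). Other scalings and floors were not run for the list. Of 382 values of 51 named or listed GeneChip genes under other settings, 375 kept direction and side of the threshold, 3 passed with the block, and 4 changed sign. NFE2L2 ranged from -0.67 to 0.43 and GAPDH from -3.28 to 0.46 without any 1 array, neither past the threshold. For 105 oligoarray genes, taken as the mean of a gene's rows, all 210 values under other centring or scaling kept both. Of 96 values of 32 genes without 1 array, 60 kept both and 36 lost the threshold. In the fits of single rows used in the report, of 32 named rows called with all arrays, 0 were called without array 1, 0 without array 2 and 30 without array 3. The GeneChip changes spread more among genes of low signal. Their median SD over harvests was 0.894 in the fifth of shared genes with the lowest signal and 0.368 in the highest.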

Other observations

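Among the lists not described so far, glycolysis and hypoxia genes had 11 of 21 oligoarray ratios below 1 and 4 above (median -0.19). PKM (-1.96 ± 0.07), GAPDH, the mutase PGAM1 (-0.82 ± 0.03) and the lactate dehydrogenase LDHA (-0.78 ± 0.07) were among them. On the GeneChips 12 of 19 members had a higher mean and none passed. Noradrenergic and neuroblastoma identity genes had 9 of 17 below 1 and 4 above (median -0.22), with TH, the first enzyme of catecholamine synthesis, at -1.12 ± 0.19, MYCN at -0.77 ± 0.03 and the catecholamine transporter SLC18A1 at 1.04 ± 0.40. On the GeneChips 7 of 14 were higher. Neuronal structure genes had 6 of 22 above, such as STMN2 (0.98 ± 0.02), and 10 below, such as L1CAM (-0.78 ± 0.26), and 16 of 24 were higher on the GeneChips, where fry passed with the block (adjusted p = 0.0312) and not without it (0.594). Camera called none of these lists on either platform (lowest adjusted p 0.229 on the oligoarrays and 0.149 on the GeneChips).

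Camera also called none of the remaining 6 lists (lowest adjusted p 0.777 and 0.138). Counts are given as above and below 1 on the oligoarrays, then as higher means on the GeneChips, where no member passed. Ribosomal proteins had 9 above and 11 below of 34 (RPS2, -0.69 ± 0.23), and 7 of 28 higher. Cholesterol synthesis had 4 and 5 of 17 (ACLY, -0.91 ± 0.03), and 7 of 14. Phase I metabolism had 3 and 1 of 12 (CYP1A2, 0.57 ± 0.11), and 3 of 5. Metallothioneins had 1 and 1 of 8 (MT3, -0.23 ± 0.02), and 5 of 7. Mesenchymal, Schwann and fibroblast markers had 6 and 6 of 21 (POSTN, -0.78 ± 0.32), and 7 of 12. Immune and endothelial markers had 2 and 6 of 15 (CD74, -1.28 ± 0.14), and 3 of 6. On the GeneChips the median and mean of cholesterol synthesis differed in sign (-0.02 and 0.05), and camera ranked endoplasmic reticulum stress down at a median of 0.01.

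The next paragraphs report tests set before their results were seen, except those of the match of rows to genes, of ratios over all shared genes without the filter and of list shifts within harvest pairs. The 3 oligoarrays correlated with each other over shared genes at r = 0.79 to 0.86 and with the GeneChips at r = 0.04. Between harvests the GeneChip changes themselves correlated at only r = -0.027 to 0.062 over these genes. The tables argue against a wholesale wrong match of rows to genes, since a share of 1e-04 of 10000 random lists, the smallest possible, had as high a median as the antioxidant response element list. A candidate explanation is that part of the ratio belongs to the probe and not to the gene: for 496 genes with 2 probes, the ratios correlated at r = 0.226 (bootstrap 0.129 to 0.325), and of 125 genes with both probes called, 39 pairs had opposite signs. Ratios at genes without GeneChip signal stay open: the median absolute ratio in the fifth with the lowest signal was 0.955 times that of the others (bootstrap 0.879 to 1.04) among 5030 genes past the filter, which had removed the dimmest genes, and 1.19 times (1.11 to 1.29) over all 7377 shared genes. Error of the GeneChip changes stays open, since the platforms' correlation was 0.0906 in the fifth with the highest signal, where the changes of separate harvests correlated at 0.0263, and a difference between the cultures of the sets and a dye bias of single probes were not tested.

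For the GeneChip comparison of tBHQ with vehicle, the real split called 0 probe sets, so that 35 of 35 splits necessarily called as many and their number says nothing about chance. The highest other count was 11, for harvests 1 and 2 against harvests 3 and 4, a split that follows the harvest days. With the harvest block the real split called 3, and the highest of the other splits that part all 4 pairs called 0 (1 of 8 as large); 8 splits are too few for a share under 0.05. The mean shift of the antioxidant response element list was 0.794, and 1 of 35 splits, the real one, was as large, with the highest other at 0.748. That is the smallest share that 35 splits can give, and these splits ignore the harvest pairs. Within the harvest pairs 1 of 8 splits was as large, too few for a share under 0.05. Chance is therefore not excluded for this list. The list's median change was 0.530, 0.860, 0.492 and 0.339 in harvests 1 to 4.

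The tBHQ arrays of harvests 1 and 2 correlated at r = 0.966, above the 0.852 to 0.923 of arrays that shared a harvest. EEF1A1 had a signal of 144160 ± 19886 (SD, n = 4) in vehicle and 79074 ± 33916 (SD, n = 4) with tBHQ and was lower in 4 of 4 harvests.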
